A study of Rattus norvegicus with 4 samples.

How the data were processed

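RNA of visceral adipose tissue from male Wistar rats, 130 days old per the labels, was measured on 4 single-colour arrays, 2 of control and 2 of obese animals per the labels' titles. The deposited table gives 1 intensity per probe set and array on a linear scale, from the values: none is negative and the highest is 5022.9. The scanner settings, the software and the normalization by the authors are not given in the sources used here. From the values, the authors' deposited intensities had been scaled, because the mean signal after trimming 2% of probe sets at each end lay between 150.026 and 150.03 on the 4 arrays. Under a rule set before the data were examined, values whose trimmed means lie within 5% were used as deposited. No detection call or background value was used, so a dim signal has only the bound given by the floor.

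The table holds 15923 probe sets, of which 57 control probe sets were left out. Of the remaining 15866, the platform's annotation pairs 12783 with 1 gene symbol, 312 with several and 2771 with none, and only the first kind was named. Symbols were looked up through Entrez gene identifiers in a table of the rat assembly GRCr8, which held 12748 of them and changed 0, and the other 35 kept the platform's symbol. Values were raised to a floor of 20.8, the 20th percentile over all arrays, and log2 was taken. A probe set was tested when at least 2 of the 4 arrays lay above the floor, which left 12929 probe sets of 9012 genes. A gene with both arrays of a group at or under the floor is given as at least N-fold, the other group's mean log2 signal against the floor. For 7 named genes (Ankrd17, Sctr, Adrb1, Adra2a, Gzmb, S100a9 and Snap25) 1 array of a group lay at or under the floor, so the size of their log2 difference depends on the floor.

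Probe sets were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend of variance on mean level), obese minus control, two-sided, with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. Errors of log2 differences are the moderated standard errors of that fit, with 5.83 degrees of freedom. With 2 arrays per group an exact permutation test cannot give a two-sided p below 0.333, so none was run, and probe sets whose groups did not overlap and differed at least 2-fold were counted as a description. Gene lists were compared with limma's camera at a preset correlation of 0.01 between genes, adjusted over 36 lists, on 1 probe set per gene, the one with the highest mean. A list needed at least 5 measured genes. The 36 lists held 896 entries, of which 747 matched a probe set of 1 gene. Members were also adjusted over their list alone.

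The lists covered adipokines, de novo lipogenesis, triglyceride storage, lipolysis, fatty acid oxidation, respiratory chain, tricarboxylic acid cycle, brown fat, insulin signalling, glycolysis, cholesterol synthesis and adipogenic transcription factors. Further lists held markers of macrophages, lymphocytes, mast cells, endothelium, smooth muscle, mesothelium and epithelium, epididymis, pancreas, skeletal muscle, blood, adrenal, kidney and liver, and nerve. The others were inflammatory cytokines, MHC class II, interferon response, extracellular matrix, glucocorticoid response, immediate early, antioxidant, clock, cell cycle, ribosomal, proteasome and endoplasmic reticulum stress genes.

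Named genes followed a rule set before the data were examined. It took up to 12 genes in each direction past the threshold, filled up with the smallest unadjusted p among probe sets that were separated and at least 2-fold apart. It also took from each list the members with the largest and the smallest t and the 2 with the highest mean log2 signal, and always Lep, Adipoq, Fasn, Scd, Ucp1, Lpl, Pparg, Cd68 and Tnf. The members picked by that signal are given here only for the 7 lists that kept their call whichever array was left out. Genes that passed over their list alone were named too.

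The alternatives were 3 other scalings, other floors, a pseudocount in place of the floor, other filters on dim probe sets, other variance models, a plain test, a replicate block, each array left out in turn, an estimated correlation, the rotation test fry and the mean over a gene's probe sets. Without 1 array, the lone array of its group is assumed to vary like the other group. The code was tested on simulated data for obese against control with 2 arrays each and 12929 probe sets, drawn from the real means and the real spread with independent genes. Of 200 changed genes per draw over 20 draws, 94.4% of those changed 4-fold and 38.9% of those changed 2-fold were called, with 4.7 false calls per draw. The changed genes were drawn only from probe sets with a mean well above the floor, so these shares do not cover dim probe sets. In the same draws, 70.25 unchanged probe sets per draw were separated and at least 2-fold apart. Camera called 0 lists when none was shifted, and called both lists in each draw when 2 were shifted by 0.4. The simulated genes were independent, which the preset correlation nearly assumes. These draws therefore cannot show how often camera calls unshifted lists of correlated genes, and no smaller shift was tried. Figures were drawn with matplotlib.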

Results

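Visceral adipose tissue of male Wistar rats aged 130 days was profiled on single-colour oligonucleotide arrays. The labels divide the 4 arrays into 2 control and 2 obese samples, and they do not say how obesity arose. The title of obese replicate 1 is Obese rat 1, and no other label says whether a sample was 1 animal or a pool. The limma p-values below therefore measure only the spread between these samples, which may be technical. Camera p-values at the preset correlation set a list's genes against the other genes and take genes as nearly independent. They do not measure the spread between animals. The median signal was 82.9 and 82.6 on control replicates 1 and 2, and 81.9 and 74.9 on obese replicates 1 and 2. Across the 12929 tested probe sets, the log2 signals of the 2 control arrays correlated with r = 0.976 and those of the 2 obese arrays with r = 0.966, while pairs from different groups gave 0.961 to 0.969. The ratio of 3' to 5' control probes was between 1.05 and 1.19 for actin and between 0.952 and 1.04 for GAPDH. The number of arrays, 2 per group, limits the precision of every value.

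The comparison asked how gene expression in visceral fat differed between obese and control rats. Lists of genes of fatty acid synthesis and of the mitochondrial respiratory chain rose in the obese samples, and lists of macrophage, MHC class II and lymphocyte markers fell, in camera with a preset correlation between genes. None of these 5 calls held with the correlation estimated for each list (adjusted p = 0.525 to 0.560 with an estimated correlation). That test rests on the residual degrees of freedom of 4 arrays, and its power was not measured, so the losses leave the 5 calls open. Regrouping the arrays by replicate number, which mixes the groups, passed 11 lists at the preset correlation, and the remaining regrouping passed 14. The respiratory chain list passed in both, the lymphocyte list in the first and the lipogenesis list in the second. The lymphocyte call also ended without control replicate 1 (median -0.21). Fatty acid synthase, Fasn, had a signal of 1291 ± 218 (SD, n = 2) in obese and 531.9 ± 65.5 in control tissue, a log2 difference of 1.28 ± 0.17 (SE). The macrophage glycoprotein Gpnmb had a signal of 604.9 ± 233 in obese and 2186 ± 626 in control tissue, a log2 difference of -1.88 ± 0.32. The matrix genes Tnc (tenascin C) and Spp1 (osteopontin) differed by -2.26 ± 0.18 and -2.34 ± 0.37. These 4 genes did not pass the limma test over all probe sets (adjusted p = 0.273, 0.402, 0.137 and 0.371), and each passed when adjusted over its list alone.

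With limma's moderated test, 0 of 12929 probe sets passed at an adjusted p of 0.05, and 1073 had an unadjusted p under 0.05, where chance gives 646.45. A plain test without moderation also passed 0 and put 882 under an unadjusted p of 0.05. A fit with an array left out judges the lone array of its group by the other group's spread, so its number of passing probe sets is not given. The groups did not overlap and differed at least 2-fold for 147 probe sets, 53 higher and 94 lower in obese tissue. This number was 304 (80 higher) without obese replicate 1, 238 (89 higher) without control replicate 1, 225 (115 higher) without obese replicate 2 and 176 (76 higher) without control replicate 2. It was 149 (68 higher) with median centring, 148 (63 higher) with quantile normalization and 147 (62 higher) with cyclic loess. Of all tested probe sets, both obese arrays lay above both control arrays for 15.6% and below them for 24.4%, where chance gives 16.7% for each direction. These shares were 18.8% and 20.6% with quantile normalization, 19.4% and 20% with cyclic loess, and 21.8% and 16.9% with each array centred on its median, the only scaling of the 3 with more probe sets above than below.

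Among genes with non-overlapping groups at least 2-fold apart, the smallest p-values for higher signals in obese tissue belonged to Clec3b, Fasn, Cldn19, Skic2, Npy, Rbm24, Cyp11a1, Itih3, Ankrd17, Gpt, Dusp1 and Rnase1l2. None of these 12 passed over all probe sets (limma, adjusted p between 0.273 and 0.467). Clec3b, which encodes the plasminogen-binding protein tetranectin, had the largest measured difference, 3.05 ± 0.41, from a signal of 27.1 ± 3.68 to 244.1 ± 139, and 2.03 with the floor at the 40th percentile. Npy, neuropeptide Y, differed by 1.99 ± 0.38, Cyp11a1, the first enzyme of steroid synthesis, by 1.15 ± 0.23, and Gpt, alanine aminotransferase, by 1.11 ± 0.24. The log2 difference was 1.02 for Itih3, 1.12 for Rbm24, whose second probe set gave 0.53, and 1.10 for the phosphatase Dusp1, whose second gave 0.78. Ankrd17 gave 1.52 with 1 probe set and -0.13 with the other. In control tissue the signals of Cldn19, Skic2 and Rnase1l2 lay at or under the floor of 20.8 on both arrays, so that obese tissue was at least 2.97-fold, 2.07-fold and 7.48-fold higher. For Rnase1l2 this bound was 3.44-fold without obese replicate 1 and 16.3-fold without obese replicate 2.

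The 12 genes lower in obese tissue were Prss35, Tnc, Cst6, Dnase1l3, Ptprc, Mfap4, Sctr, Laptm5, Lcp2, Irf8, Ptn and Tnn, with adjusted p between 0.0701 and 0.280 in limma, so that none passed. The serine protease-like gene Prss35 had the smallest p, with a signal of 151.1 ± 3.25 (SD, n = 2) in control tissue and both obese arrays under the floor, at least 7.26-fold lower in obese tissue. The same bound was 5.09-fold for Cst6, a cysteine protease inhibitor, and 2.53-fold for Tnn, tenascin N. Mfap4, a microfibril-associated protein, differed by -1.84 ± 0.22, and Dnase1l3 by -1.58 ± 0.17. Genes of blood cells were among the 12: Ptprc (CD45) differed by -1.36 ± 0.15 (-0.87 with its second probe set), the adaptor Lcp2 by -1.41 ± 0.18 (-1.11 with its second, and -0.77 with the floor at the 40th percentile), the transcription factor Irf8 by -1.22 ± 0.16 and the lysosomal protein Laptm5 by -1.09 ± 0.13. Sctr, the secretin receptor, differed by -1.85 and Ptn, pleiotrophin, by -1.16.

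**Figure D1:**
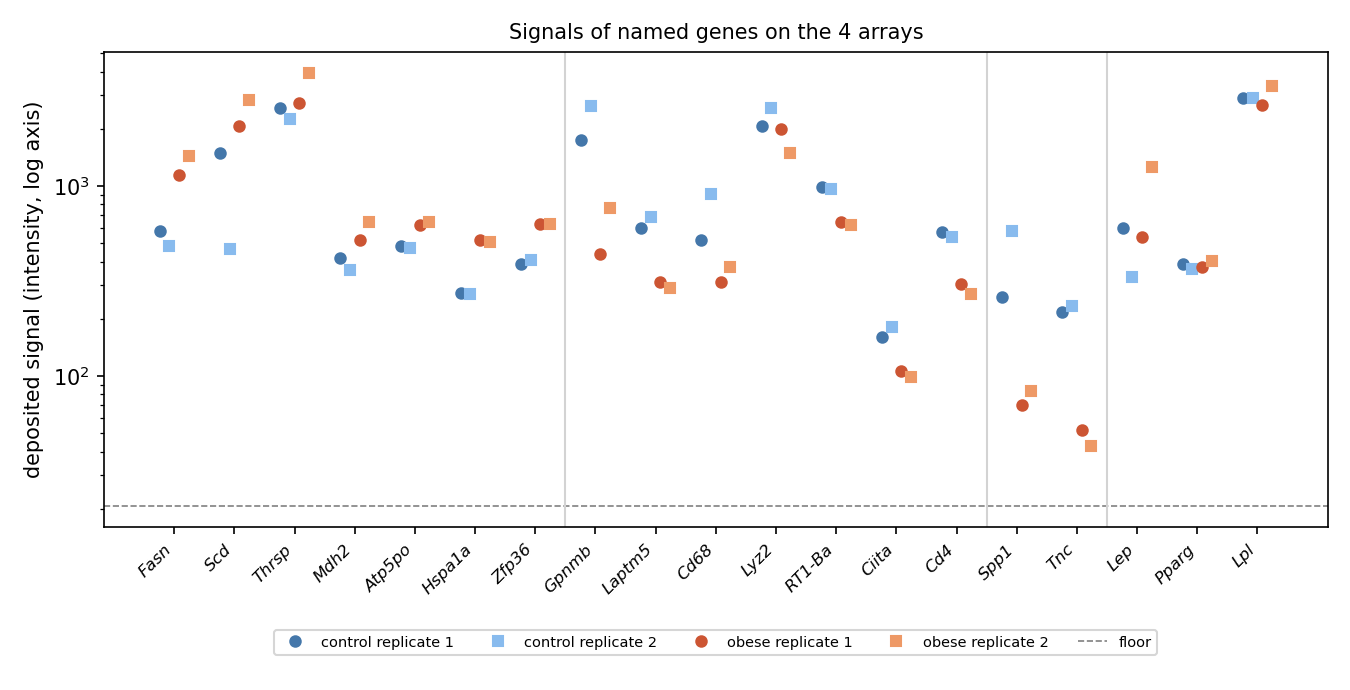
Deposited signal (intensity, log axis) of 19 named genes on each of the 4 arrays, with the dashed line at the floor of 20.8. Each point is 1 array, and for Fasn both obese arrays lie above both control arrays, whereas for Gpnmb and Tnc both lie below.

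Of 36 gene lists fixed before the data were examined, 20 passed limma's camera test with a preset correlation of 0.01, 15 higher and 5 lower in obese tissue. With the correlation estimated for each list, 0 of 36 passed, and their smallest adjusted p was 0.525. The rotation test fry passed 1 list, MHC class II (adjusted p = 0.0334). Regrouping the same arrays as replicate 1 against replicate 2 of both groups passed 11 lists in camera, and the remaining regrouping passed 14. The respiratory chain list passed in both (camera adjusted p = 0.0164 and 0.00331), the lymphocyte list in the first (8.10e-05) and the lipogenesis list in the second (0.000188). Of the 20 lists, 8 passed in neither regrouping, and 7 kept their call whichever array was left out. Macrophage, MHC class II, immediate early and antioxidant lists did both. The glucocorticoid list shared 6 genes with other lists, and the other passing lists shared at most 2 each.

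The list of de novo lipogenesis, the synthesis of fatty acids from acetyl-CoA, was higher in obese tissue for 23 of its 24 measured genes, with 15 genes fully separated where chance gives 4. Its median log2 difference was 0.36 (camera adjusted p = 3.65e-09, adjusted p = 0.528 with an estimated correlation). Here and below, the chance number of separated genes is an average without a spread. Genes that vary together are also separated together, so a count far above it can be common. The stearoyl-CoA desaturase gene Scd had a difference of 1.55 ± 0.53, with signals of 2451 ± 532 in obese tissue and of 1486.5 and 463.4 on the 2 control arrays (limma adjusted p = 0.552), and it was 2.39 without control replicate 1 and 0.70 without control replicate 2. Fasn alone passed when adjusted over the list alone (adjusted p = 0.00861), and both of its probe sets were higher. Thrsp and Elovl5, named by the rule on mean log2 signal, differed by 0.44 and 0.35, and Scd2 by -0.10. Thrsp and Elovl5 gave 0.18 and 0.08 without obese replicate 2, and 0.70 and 0.62 without obese replicate 1. Of the list's genes, 2 are also in other lists. Without obese replicate 2 the median was 0.19.

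Genes of the respiratory chain and ATP synthase were higher for 35 of 36 members, 26 of them separated where chance gives 6, and the list rose by a median of 0.28 (camera adjusted p = 2.47e-12, adjusted p = 0.528 with an estimated correlation). Atp5po had the largest t, with a difference of 0.41 ± 0.12, and Atp5f1b and Cox8a differed by 0.17 and 0.20. Cox8a gave 0.04 without obese replicate 2 and 0.36 without obese replicate 1. Ndufs3 gave -0.00048, a sign that turned to 0.08 with median centring. None of the 36 genes passed when adjusted over the list alone. The tricarboxylic acid cycle list rose by a median of 0.21, with 13 of 15 genes higher and 12 separated upwards (camera adjusted p = 0.000443, adjusted p = 0.528 with an estimated correlation). Malate dehydrogenase Mdh2 differed by 0.59 ± 0.16, Mdh1 by 0.28, citrate synthase Cs by 0.18 and Idh2 by -0.33. Mdh1 gave 0.05 without obese replicate 2 and 0.51 without obese replicate 1, and Idh2 gave -0.20 without control replicate 2. Over the list alone, 0 of the 15 passed. These 2 lists share 0 genes with other lists.

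Further lists of fat and energy metabolism passed camera, and the 5 given next lost their call without obese replicate 2. The lipolysis list had a median of 0.25 and 15 of 17 genes higher (camera adjusted p = 0.000635, adjusted p = 0.528 with an estimated correlation). Within it G0s2, an inhibitor of adipose triglyceride lipase, rose by 0.70 ± 0.16 when adjusted over the list alone (limma adjusted p = 0.0461), and Adra2a differed by -0.56. Adrb1, the beta-1 adrenoceptor, passed over the list alone as well, but its control signals were 22 and 6.7, so the size of that difference depends on the floor. Fatty acid oxidation had a median of 0.14 and 20 of 22 genes higher (camera adjusted p = 0.000635, adjusted p = 0.560 with an estimated correlation), with Acaa2 at 0.64 and Cpt1a at -0.19. Glycolysis had a median of 0.17 and 14 of 18 higher (camera adjusted p = 0.00135, adjusted p = 0.528 with an estimated correlation), with Gpi at 0.55 and Slc16a3 at -0.19. Triglyceride synthesis and storage had a median of 0.15 and 16 of 24 higher (camera adjusted p = 0.00333, adjusted p = 0.688 with an estimated correlation). Its gene Plin4 was at 0.62 (0.40 without obese replicate 2). Plin2, whose groups overlapped, was at -0.77 (-0.26 without control replicate 2, -1.27 without control replicate 1). Cholesterol synthesis had a median of 0.23 and 12 of 15 higher (camera adjusted p = 0.0116, adjusted p = 0.528 with an estimated correlation). Its gene Insig1 was at 0.65 (0.32 without obese replicate 2, 0.99 without obese replicate 1) and Srebf2 at -0.35. Over the list alone, 0 genes passed in these last 4 lists. Without obese replicate 2 the medians were 0.09 for lipolysis, 0.08 for fatty acid oxidation, 0.07 for glycolysis, 0.05 for triglycerides, where the test also turned direction, and 0.12 for cholesterol. The cholesterol call also ended without control replicate 1 (median 0.29). Without obese replicate 1 the medians were 0.30, 0.30, 0.27 and 0.40 for fatty acid oxidation, glycolysis, triglycerides and cholesterol, and without control replicate 2 cholesterol had 0.35. With median centring they were 0.22, 0.26 and 0.23 for fatty acid oxidation, glycolysis and triglycerides, and cyclic loess gave 0.10 for triglycerides.

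Macrophage and myeloid markers fell by a median of 0.51 on the log2 scale, with 24 of 25 measured genes lower and 19 separated downwards where chance gives 4.17 (camera adjusted p = 2.13e-10, adjusted p = 0.525 with an estimated correlation). The chance value is low for these data, since 24.4% of all tested probe sets were separated downwards. Adjusted over the list alone, 7 genes fell (limma), namely Gpnmb, Laptm5, Mmp12, Cd53, Lcp1, Ctss and Cd68, against 0 over all probe sets. Macrosialin, Cd68, had a signal of 345.1 ± 44.5 (SD, n = 2) in obese and 714.4 ± 272 in control tissue, a difference of -1.0 ± 0.27 (adjusted p = 0.0385 over the list alone in limma, 0.488 over all). Without control replicate 2, Cd68 gave -0.60 and Lcp1 -0.64. Macrophage elastase Mmp12 differed by -1.06 ± 0.20 (-0.44 with the floor at the 40th percentile), Lcp1 by -1.04 ± 0.26, Cd53 by -0.95 ± 0.17 and cathepsin S, Ctss, by -0.51 ± 0.13. Lysozyme Lyz2 and galectin-3 Lgals3 differed by -0.43 and -0.51, and by -0.27 and -0.32 without control replicate 2. Lyz2 gave -0.22 without obese replicate 2. The complement genes C1qa, C1qb and C1qc, named after their values were seen, differed by -0.20, -0.15 and -0.03, and Cd48 by 0.12. Without control replicate 2, the array with the highest macrophage signals, the median was -0.32.

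MHC class II and antigen presentation genes fell by a median of 0.39, with 13 of 14 genes lower and 10 separated downwards (camera adjusted p = 2.54e-06, adjusted p = 0.525 with an estimated correlation). Chance gives 2.33 genes separated downwards, and the share over all tested probe sets was 24.4%. Over the list alone 6 genes fell (limma), the class II transactivator Ciita (-0.74 ± 0.16), RT1-Ba (-0.63 ± 0.12), RT1-DMa (-0.61 ± 0.14), RT1-DMb (-0.59 ± 0.17), RT1-Db1 (-0.54 ± 0.12) and Ctss, which the macrophage list also holds. The invariant chain Cd74 differed by -0.33. The class I light chain B2m gave 0.08, and -0.02 with cyclic loess. The lymphocyte list fell by a median of 0.49, with 19 of 20 genes lower (camera adjusted p = 7.63e-05, adjusted p = 0.560 with an estimated correlation). Within it Cd37 differed by -1.20 ± 0.22 and Cd4 by -0.96 ± 0.13 and passed over the list alone, and Gzmb differed by 0.56. Without control replicate 1, on which the T cell gene Cd3d had a signal of 77.7 against 23.3 to 28.8 on the other arrays, the lymphocyte median was -0.21 and the call ended (camera adjusted p = 0.0644). Without control replicate 2 the median was -0.98. Endothelial markers had a median of -0.01 and did not pass (camera adjusted p = 0.832), with Cldn5 at 0.26 and Tie1 at -0.45.

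The extracellular matrix list fell by a median of 0.18, with 26 of 43 genes lower and 18 separated downwards (camera adjusted p = 0.00326, adjusted p = 0.528 with an estimated correlation). Chance gives 7.17 genes separated downwards, and the share over all tested probe sets was 24.4%. Over the list alone 4 genes fell (limma), Tnc, Spp1, biglycan Bgn (-0.65 ± 0.14) and gelatinase B, Mmp9, which was under the floor on both obese arrays and at least 2.13-fold lower there. Connective tissue growth factor, Ccn2, differed by 0.81. Without obese replicate 1 the median was -0.07 and the call ended (camera adjusted p = 0.276), and with median centring the median was -0.10.

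Immediate early and heat shock genes rose by a median of 0.13, with 19 of 27 genes higher and 13 separated upwards (camera adjusted p = 5.42e-05, adjusted p = 0.525 with an estimated correlation). Over the list alone 4 genes rose (limma), the heat shock protein Hspa1a (0.92 ± 0.12), Dusp1 (0.78 ± 0.13), Zfp36 (0.66 ± 0.12) and Myc (0.77 ± 0.19). Hspb1 differed by 0.44 and Atf3 by -1.04 (-0.59 without obese replicate 2). Without control replicate 2 the median was 0.26, and without obese replicate 1 it was 0.29. It was 0.27 with the filter on the mean, 0.25 and 0.21 with the floor at the 40th and 10th percentile, and 0.20 with cyclic loess. Antioxidant and xenobiotic enzymes rose by a median of 0.18, with 23 of 31 higher (camera adjusted p = 3.07e-05, adjusted p = 0.525 with an estimated correlation), while 0 passed over the list alone. Cyp1b1 differed by 1.53 ± 0.40 (0.97 without obese replicate 2) and heme oxygenase Hmox1 by -1.04 ± 0.46 (-0.28 without control replicate 2, -1.80 without control replicate 1). Gpx3 differed by 0.31 (0.18 without obese replicate 2) and Mgst1 by 0.17 (0.014 without obese replicate 2, 0.32 without obese replicate 1). Without obese replicate 1 the antioxidant median was 0.30. The glucocorticoid list rose by a median of 0.20, with 9 of 13 genes higher (camera adjusted p = 0.00326, adjusted p = 0.528 with an estimated correlation). Over the list alone Sgk1 (0.71 ± 0.16) and Dusp1 rose, and Akr1c14 differed by -0.18. Without control replicate 2 its median was 0.03 and the call ended (camera adjusted p = 0.603), and it was 0.13 with cyclic loess and 0.05 without the filter on dim probe sets.

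**Figure D2:**
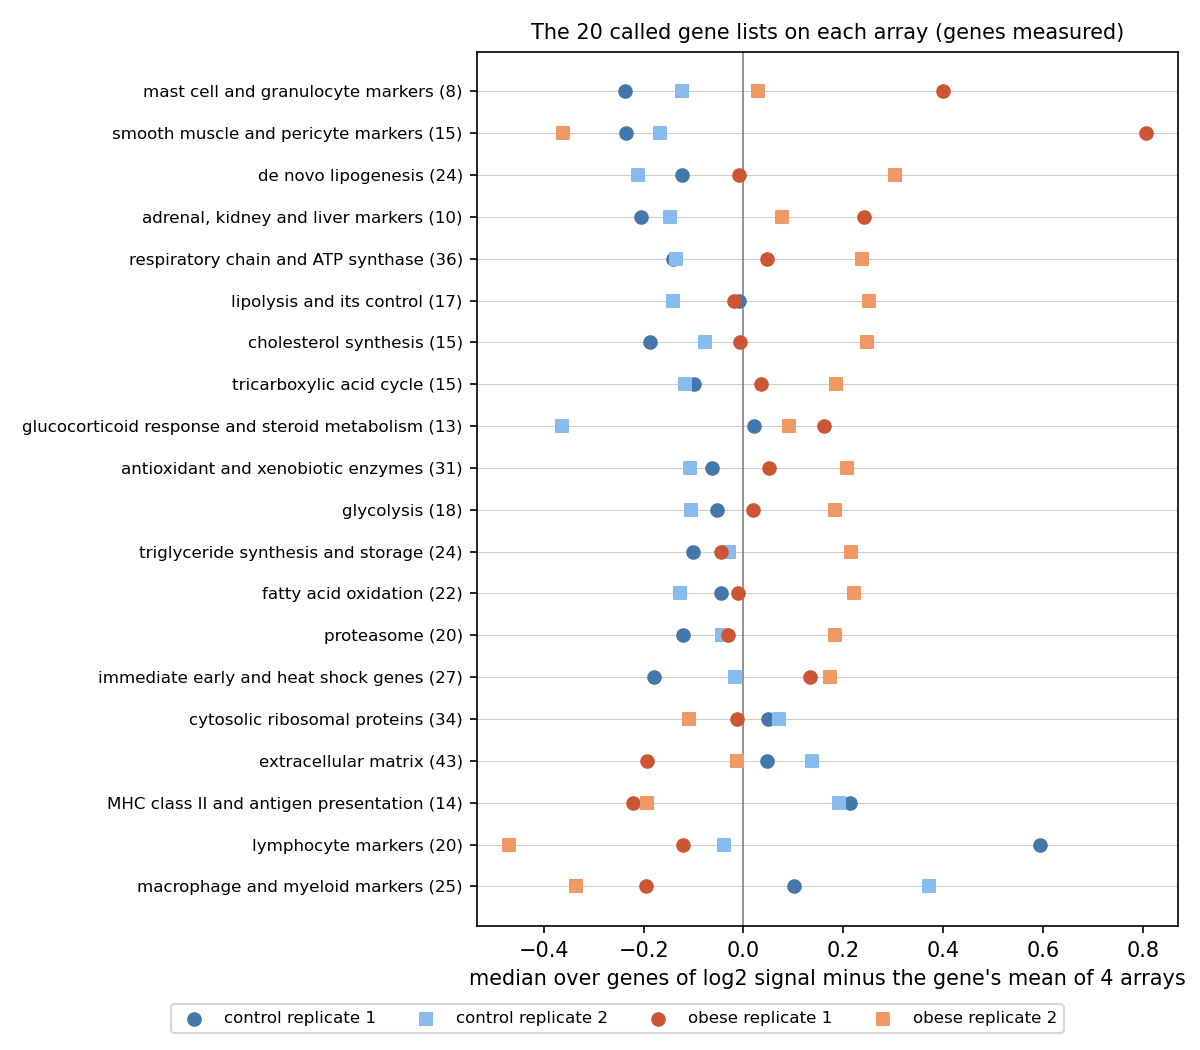
The 20 gene lists that passed camera, with the number of measured genes in parentheses. Each point is the median over a list's genes of the log2 signal on 1 array minus the gene's mean of 4 arrays. Both obese arrays lie below both control arrays for the macrophage list, and obese replicate 1 stands at 0.81 for smooth muscle.

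Genes of tissues that can adjoin or run through visceral fat were measured as 7 further lists. Smooth muscle and pericyte markers had a median of 0.43, with 13 of 15 higher (camera adjusted p = 0.00333, adjusted p = 0.630 with an estimated correlation). Myl9 was at 0.68 and Rgs5 at -0.20. They gave 0.22 and -0.34 without obese replicate 1, and 1.15 and -0.06 without obese replicate 2. The list's median was 1.15 without obese replicate 2, and -0.15 without obese replicate 1, on which its value rested. On that array the intestinal-type actin Actg2 had a signal of 675.1 against 77.4 to 91.5 on the other 3, keratin 5, Krt5, had 396.8 against 44.2 to 49, and pancreatic lipase, Pnlip, had 496.8 against 29 to 44.7. Pancreas and intestine markers did not pass (camera adjusted p = 0.308), with Cpb1 at 1.65 (0.33 without obese replicate 1, 2.96 without obese replicate 2) and Cpa1 at -1.34 (-0.30 without control replicate 2, -2.37 without control replicate 1), and neither did mesothelial and epithelial markers (adjusted p = 0.308), with Igfbp5 at 0.24 and Msln at -0.46. Adrenal, kidney and liver markers rose by a median of 0.35, with 8 of 10 higher (camera adjusted p = 0.00326, adjusted p = 0.528 with an estimated correlation). Its genes Cyp11a1 and Star, which transports cholesterol into mitochondria and differed by 1.47 ± 0.39 (0.95 without obese replicate 2), passed over the list alone, and Th differed by -0.42. Without obese replicate 1 that median was 0.19 and the call ended (camera adjusted p = 0.0941), and without obese replicate 2 it was 0.54. With the floor at the 10th percentile it was 0.02, and without the filter on dim probe sets 0. Epididymis and testis (adjusted p = 0.303) and skeletal muscle (0.644) did not pass camera. Adam7 differed by 0.13, Tnni2 by 0.53 and Tnnt3 by -0.30, and Cd52 was under the floor on both obese arrays, at least 2.13-fold lower there. Nerve and Schwann cell markers did not pass either (camera adjusted p = 0.266), although Npy passed over that list alone, and Snap25 differed by -1.42.

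**Figure D3:**
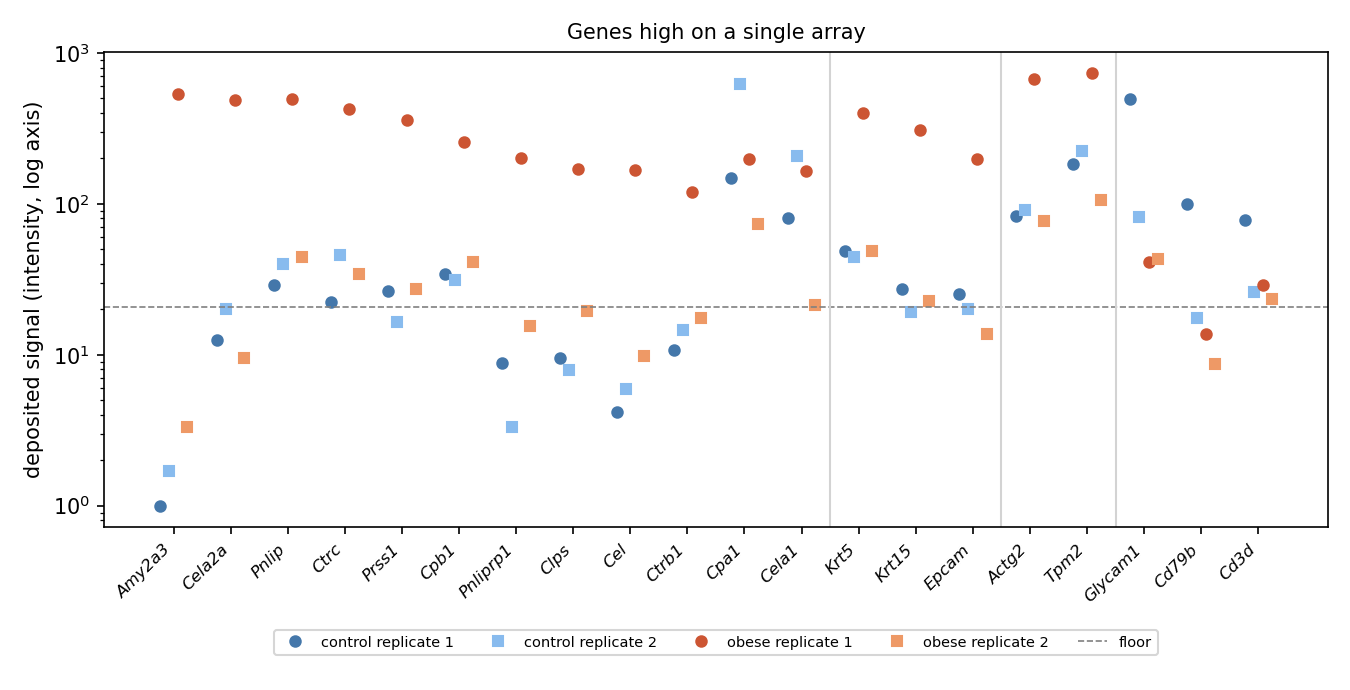
Deposited signal (intensity, log axis) of 20 genes on each of the 4 arrays, chosen after their values were seen, with the dashed line at the floor of 20.8. The first 10 genes, all pancreatic enzymes or their cofactors, stand out on obese replicate 1, whereas Cpa1 and Cela1 do not, and the last 3 genes stand out on control replicate 1.

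Mast cell and granulocyte markers had a median of 0.50, with 6 of 8 genes higher (camera adjusted p = 0.0116, adjusted p = 0.528 with an estimated correlation). Mast cell chymase, Cma1, rose by 0.94 ± 0.22 when adjusted over the list alone (limma), and S100a9 differed by -0.93 (-1.57 without obese replicate 1, -0.31 without obese replicate 2). The call ended without control replicate 1 (median 0.13) and without obese replicate 1 (median 0.31), and also with the floor at the 10th percentile (median -0.04, camera adjusted p = 0.137) and without the filter on dim probe sets (camera adjusted p = 0.260). Proteasome genes had a median of 0.14, with 16 of 20 higher (camera adjusted p = 0.000774, adjusted p = 0.548 with an estimated correlation), and Psma1 at 0.41 and Psmb1 at -0.06, which gave 0.02 with median centring. Without obese replicate 2 this median was 0.03 and the call ended, and without obese replicate 1 it was 0.25, and it was 0.22 with median centring. Cytosolic ribosomal protein genes had a median of -0.12, with 30 of 34 lower (camera adjusted p = 0.0246, adjusted p = 0.688 with an estimated correlation). Rps15a differed by 0.07, and Rpl30 was at the floor on both obese arrays, at least 1.28-fold lower. The ribosomal call ended with median centring (median -0.04), without control replicate 1 (-0.13), control replicate 2 (-0.10) or obese replicate 2 (-0.07), and cyclic loess gave -0.19.

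Leptin, Lep, had a signal of 898 ± 507 (SD, n = 2) in obese and 463.8 ± 189 in control tissue, a difference of 0.89 ± 0.45 (limma adjusted p = 0.663), and the groups overlapped. Its difference was 0.28 without obese replicate 2, 0.46 without control replicate 2 and 1.5 without obese replicate 1. The adipogenic regulator Pparg (0.04 ± 0.12) and lipoprotein lipase, Lpl (0.05 ± 0.17), differed by less than their errors, and Lpl gave -0.02 and -0.05 with quantile and cyclic loess scaling. Ucp1 of brown fat differed by -0.33 ± 0.26 from a control signal of 37.75 ± 8.84. It gave -0.09 without control replicate 1 and -0.57 without control replicate 2. Tumour necrosis factor, Tnf, had a control signal of 28.6 ± 0.707 and was under the floor on both obese arrays, at least 1.37-fold lower (limma adjusted p = 0.588). Adiponectin, Adipoq, had no probe set with that single symbol and was not analysed here.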

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

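All tests in this part were chosen after the result was seen. Several signals lay outside the comparisons of the report. The hybridization spike-in probes, which report on the array and not the tissue, had a mean log2 signal of 8.04 on obese replicate 2 against 7.56 and 7.63 on the control arrays. The GAPDH control probes had 10.65 on the same array against 10.16 and 10.23. The poly-A spike-in probes had 4.38, the log2 of the floor, on both control arrays and obese replicate 2, so no signal above it was measured there. On obese replicate 1 the mean was also 4.38 and differed only in further digits. Among the 2937 probe sets too dim for testing, 3 were at least 16-fold above both control arrays on an obese array, and 0 were so on a control array. All 3 were on obese replicate 1: the amylase gene Amy2a3 at 531.8, the elastase gene Cela2a at 484.7 and a probe set without a single gene symbol at 1445.2.

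The pattern behind the last values is a set of digestive enzyme genes on obese replicate 1. Of 13 exocrine pancreas genes on the array, 10 were at least 2-fold above every other array there, with Pnlip at 496.8, Ctrc at 426.5 and Prss1 at 361.5, against 1 gene on control replicate 2 and 0 on the other arrays. A candidate explanation is exocrine pancreas tissue in obese replicate 1, taken along with the fat, although Cpa1 (197 there, 622.5 on control replicate 2) and Cela1 did not follow, and Prss2 had at most 1.8 on any array. Keratin 5, Krt5, and Actg2 were also high on that array alone, and no biological explanation was tested.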

How the results depend on the processing

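Signal over background could not be judged without detection calls, so low signals are limited by the floor alone. The number of probe sets that passed, 0, became 3 with a pseudocount, 6 without the filter on dim probe sets, and 1 without the trend or with robust variances, and ranged from 0 to 43 with an array left out. The number separated and at least 2-fold apart, 147, was 314 with the floor at the 10th percentile, 71 at the 40th, 94 with a pseudocount and 64 with the filter on the mean, and 176 to 304 with an array left out. Fewer or more dim probe sets were tested under other filters, and with an array left out the groups fail to overlap more often by chance. The cause of the other differences was not tested. The 20 list calls became 0 with an estimated correlation and 1 with fry, and of the 20 lists 16, 18, 16 and 13 kept their call without control replicate 1, control replicate 2, obese replicate 1 and obese replicate 2. Under each other alternative 18 to 20 of them kept it. The 4 arrays allow 3 splits, too few for a share under 0.05. The real split gave 1073 probe sets under an unadjusted p of 0.05, 147 separated and 20 lists, and the highest of the other splits 514, 57 and 14.

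The labels give both groups replicate numbers 1 and 2 without saying that they pair samples, and deviations of same-numbered arrays correlated with 0.048. With a replicate block 0 probe sets and 21 lists passed, and it ended none of the 20 list calls.

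Of 125 named genes, 14 passed under some alternative, 11 of them without obese replicate 1 and 8 without obese replicate 2, while 104 were tested with the floor at the 40th percentile and 92 with the filter on the mean. With an array left out, 52 of the 125 genes and 17 of the 20 lists moved by over 1.5 times, and under another alternative 39 genes and 10 lists did. Reversals concerned 12 genes and 2 lists, and their cause was not tested. With an array left out, the triglyceride list ranged from 0.054 to 0.27, camera turning downwards at the lowest, without obese replicate 2, and the smooth muscle list from -0.15, without obese replicate 1, to 1.15. The genes ranged from -0.34 to 0.13 (Scd2), -0.45 to 0.072 (Cpt1a), -0.12 to 0.12 (Ndufs3), -0.066 to 0.40 (Atp5f1b), -0.032 to 0.20 (B2m), -1.38 to 0.46 (Msln), -0.078 to 0.33 (Adam7), -0.64 to 0.28 (Akr1c14), -0.14 to 0.28 (Rps15a), -0.13 to 0.0093 (Psmb1), -0.11 to 0.21 (Lpl) and -0.015 to 0.089 (Pparg). Median centring gave 0.079 for Ndufs3 and 0.019 for Psmb1, cyclic loess -0.019 for B2m and -0.048 for Lpl, and quantile normalization -0.024 for Lpl.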

Other observations

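All tests of explanations in this part were chosen after the result was seen. The lists not described so far did not pass camera. Adipokines (adjusted p = 0.322) held both directions, with apelin, Apln, at 0.95 ± 0.28 (0.57 without obese replicate 2) and granulin, Grn, at -0.39. Adipogenic transcription factors (0.164) had Cebpb at 0.58 and Nr1h2 at -0.27. Brown fat markers (0.346) had Cidea at 0.62 (0.31 without obese replicate 2, 0.94 without obese replicate 1). Insulin signalling (0.832) had Enpp1 at 0.67 and the insulin receptor substrate Irs1 at -0.59. Inflammatory cytokines (0.137) had a median of -0.20, with Nfkbia, the inhibitor of NF-kappa-B, at 1.01 ± 0.26 and Tgfb1 at -0.94 ± 0.25. The interferon list (0.832) had Ifit3 at 0.64 (0.34 without control replicate 2), and its gene Irf8 fell when adjusted over the list alone in limma (adjusted p = 0.0049).

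Cell cycle genes (camera adjusted p = 0.078) had a median of -0.25, with Mcm3 at -0.52 and Cdkn1a at 0.39. The clock list (0.832) had Dbp at 0.29 and Nr1d1 at -0.59, and endoplasmic reticulum stress (0.676) had Ddit3 at 0.75 and Sel1l at -0.31. In the blood list (0.832), Pf4 of platelets rose by 0.93 ± 0.23 (0.59 without obese replicate 1) and Slc4a1 of red cells fell by 1.26 when adjusted over the list alone in limma (adjusted p = 0.0225 for each). The test's direction differed from the sign of the median for 4 lists that did not pass: skeletal muscle (median -0.03, mean 0.02, upward), blood (0.02, -0.11, downward), clock (-0.01, -0.02, upward) and endoplasmic reticulum stress (-0.03, 0.02, upward).

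Each array had tested probe sets at least 2-fold above all the others: 61 on obese replicate 1, 29 on obese replicate 2, 19 on control replicate 1 and 23 on control replicate 2. Genes named here were chosen after their values were seen. On control replicate 1 the lymph node venule gene Glycam1 had a signal of 493.9 against 41.2 to 82.2, and Cd79b, Tcf7, Lck and Cd8a were at least 2-fold above the other arrays. On control replicate 2 the genes Spp1 (579.1), Hmox1 (907.6), Alox15 (491.2), Mki67 (87.1) and Top2a (104.6) were so. Obese replicate 2 was at least 2-fold below all others for 56 probe sets, against 7 to 12 on each other array, and its mesothelial gene Msln had 164.7 against 375.1 to 590.7.

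Macrophage, MHC class II and lymphocyte markers were lower on both obese arrays. An equally lower share of every cell type other than adipocytes would lower endothelial markers alike. The endothelial median lay 0.51 above the macrophage median (95% bootstrap interval over genes, with the arrays held fixed, 0.30 to 0.68), and 0.30 to 0.53 with an array left out. That argues against such a share as the sole cause. It does not exclude it as a part, since the macrophage, lymphocyte and endothelial lists were all lowest on obese replicate 2. Lymphoid tissue in control replicate 1 is argued against for the macrophage and class II part, since the macrophage median was -0.59 without that array, but it may account for the lymphocyte part, whose median was then -0.21. Another scaling left the macrophage median at -0.43 or further from 0, with all 3 lists still past camera at the preset correlation, though in the deposited scaling each call was lost with the correlation estimated (adjusted p = 0.525, 0.525 and 0.560 with an estimated correlation). What stays open is a difference in these cells that comes with obesity, which was not tested, and any difference in sampling between the groups.

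Lipogenic and respiratory chain genes were higher on the obese arrays. The lipogenesis median was 0.32 with quantile normalization, 0.31 with cyclic loess and 0.44 with median centring, which argues against the scaling as the sole cause. Both lists also passed camera at the preset correlation under each of them. Camera sets a list against the other genes, so it is a weak test of a shift common to all genes. In the deposited scaling both calls were lost with the correlation estimated (adjusted p = 0.528 for both with an estimated correlation). Without obese replicate 2, on which most metabolic lists were highest, the lipogenesis median was 0.19 and the respiratory chain median 0.20. As deviations from each gene's mean, the lipogenesis medians were -0.12 and -0.21 on control replicates 1 and 2. They were -0.0098 on obese replicate 1 and 0.30 on obese replicate 2. For the respiratory chain they were -0.14, -0.13, 0.046 and 0.24. The regrouping of control replicate 1 with obese replicate 2 gave a lipogenesis median of 0.23 in size. How much rests on obese replicate 2 therefore cannot be settled with 2 arrays per group. The hybridization spike-in probes, which do not depend on the tissue, also had their highest mean log2 signal on that array. It was 8.04 there against 7.54 to 7.63 on the other arrays, and any bearing on these lists was not tested. A higher share of adipocyte RNA cannot be told apart here from a change within adipocytes. Endothelial markers, which it would lower, differed by a median of -0.0076 between the groups (95% bootstrap interval over genes, with the arrays held fixed, -0.12 to 0.10). However, 5 of 8 lists of other cell types were lowest on obese replicate 2. These were the lists of macrophages, lymphocytes, endothelium, smooth muscle, and mesothelium and epithelium. A response of adipocytes to obesity or to feeding state could give such a pattern, and neither was tested.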
